A study of Homo sapiens with 18 samples.

How the data were processed

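The series measured total RNA from cells labelled HT-29, grown in DMEM with 10% serum. Per the labels, TruSeq version 2 libraries were sequenced as paired-end reads on an Illumina NovaSeq. The genotype label put 6 libraries each into the groups CHD2 knockdown, wild type and CHD2 overexpression, and libraries are numbered 1 to 6 within a group as in their titles. The labels do not say how CHD2 was knocked down or overexpressed, whether the 6 libraries came from separate cultures, or when each was made.

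The authors deposited a single table of 58294 genes by 18 libraries in log2-like units, made by a variance-stabilising transformation of normalised gene-level values. The submitters' processing notes name CASAVA 1.8.2, Salmon, MultiQC, R 3.6.2, DESeq2 and the build hg38. The role of each, the annotation, any filter and the use of strand are not given in the sources used here. All 58294 gene identifiers, with their versions, occur in GENCODE release 29, from which symbols and coordinates were taken.

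The lowest deposited value, 9.70, was shared by all 18 columns, filled 58.3% of the cells and stood for a count of 0, and 21085 genes had it in every library. Normalised counts were calculated back from the deposited values with the form of the variance-stabilising transformation, with the lowest value as its origin. This was checked on genes with a single transcript: their low values should lie at whole multiples of the value of 1 read. In each library 86.7% to 99.3% of these values lay within 0.15 read of a whole number, where chance gives 30%. A single read was worth 0.767 to 1.24 normalised counts, which gave approximately 18755290 to 28775187 assigned fragments and 21739971 to 24953511 normalised counts per library. For genes with a single transcript the variance over the mean, close to 1 by counting alone, had medians of 1.47 to 1.66 in the groups at 300 to 1000 normalised counts and of 1.76 to 2.33 at 1000 to 3000, so at this depth both counting and the spread between libraries limit precision there. In data simulated with counting noise and 1 small dispersion for all genes, 80.4% of 1.1-fold changes and 100% of 1.25-fold changes were called. There were 11 false calls among 8364 genes. Over all genes the measured variance over the mean had medians of 2.55 to 2.65 in the groups at 300 to 1000 normalised counts. This is more than in the simulation, so the shares called may be too high for these libraries.

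Genes were kept when their mean over all libraries was at least 1 above the lowest value, equal to about 416 normalised counts, which left 8300. The 3 groups were compared with limma 3.58.1 in R 4.3.3 by a linear model on the deposited values with 1 mean per group, an intensity trend in the variance prior and two-sided moderated tests. P-values were adjusted by Benjamini-Hochberg over the kept genes of a comparison, with a threshold of 0.05. "Rose", "fell", "higher" and "lower" are used of genes past that threshold. Differences on the deposited scale are smaller than log2 folds, most of all at low counts, where that scale is compressed. Folds are ratios of mean normalised counts, and log2 folds with SE come from the same model on log2 of the normalised count plus 1. For genes in text that missed the filter, that model was run on the 16143 genes with a mean of at least 10 normalised counts. CHD2 and CHASERR were also compared by exact permutation tests of the difference of group means. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

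Before the data were examined, the comparisons, the tests, most alternatives, the rule for naming genes and 42 gene lists with 718 genes were fixed. Of these genes 717 were matched and 438 were kept. Lists with at least 5 kept members, 31 in all, were tested with limma camera at a preset correlation of 0.01, with an estimated correlation and with fry. The rule named CHD2 and CHASERR and, in each comparison, the 10 largest rises and the 10 largest falls among well-expressed called genes with no overlap between the groups. It added up to 4 called members of each called list and the 5 genes with the largest opposite changes. Size was ranked by the difference on the deposited scale, so less abundant genes with larger folds can rank lower or be left out. Up to 2 members of each list that was not called were also due as values, and these are not printed. Some genes that the rule named are not reported here. Genes named in text outside the rule were chosen after their values were seen: ZEB1, CD68, COL1A1, CD14 and those of the gene families and short lists under the other observations.

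The replicate numbers were tested for pairing between groups. Correlations of the libraries' deviations from their group means lay between -0.170 and 0.164, 2 of 18 exceeded 0.1, and 6 of 36 libraries were closest to the one with their own number, so no pairing was used. Alternatives were no filter, a stricter filter, quantile normalization, median centring, library weights, other variance priors, a fit on 2 groups, an exact rank-sum test, a minimum difference of 1, a replicate block and leaving out each library in turn. The analysis on log2 of normalised counts and the one without knockdown replicates 1 and 2 were added after the data had been seen. Raw reads were not among the files used here, so alignment, strand use and reads shared between paralogs or pseudogenes could not be examined. These matter for keratins, ribosomal proteins, mitochondrial transcripts, UGT1A and MAGE genes.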

Results

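RNA sequencing measured gene expression in cells labelled HT-29, a human colorectal adenocarcinoma cell line with epithelial morphology. The 3 groups had different levels of CHD2, a chromodomain helicase that remodels chromatin. Whether all 3 groups came from the same HT-29 stock was not tested. The series held 18 libraries, 6 from cells with CHD2 knockdown, 6 from wild type cells and 6 from cells with CHD2 overexpression. Each library held approximately 18755290 to 28775187 assigned fragments, calculated back from the spacing of its lowest values. Values below are normalised counts as mean ± SD over the 6 libraries of a group, log2 folds carry their SE, and adjusted p-values come from limma. The p-values measure only the spread between these libraries. That spread may be technical, because no label says that the 6 libraries of a group came from separate cultures.

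Libraries of the same group were close to each other and far from those of the other groups. Spearman correlations across genes, which are not independent replicates, lay between 0.991 and 0.996 within groups. Between groups they were 0.722 to 0.729 for knockdown and wild type, 0.684 to 0.687 for overexpression and wild type, and 0.587 to 0.594 for knockdown and overexpression. Differences within groups made up 1.38% of the total sum of squares. The labels give no culture, passage, date or batch, so a batch that coincides with a group cannot be told apart from it. Nor can cell populations that had diverged or been derived separately.

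**Figure D1:**
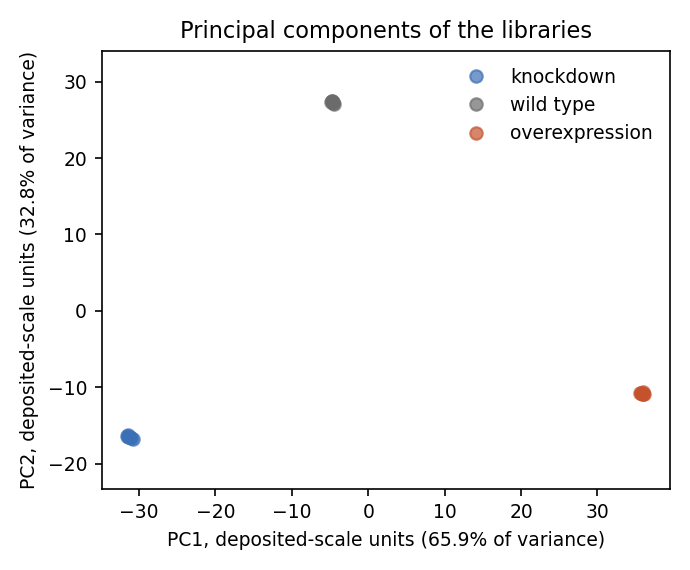
Principal components of the deposited log2-like values of 8300 genes, with 1 point per library and 6 libraries per group, which largely cover each other. The first component held 65.9% of the variance and the second 32.8%, and each group formed its own tight cluster.

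CHD2 itself (ENSG00000173575.20, chromosome 15, 92900189 to 93028005 in hg38) followed the labels in every library. Its level was 1528 ± 308 in knockdown, 3112 ± 431 in wild type and 4678 ± 463 in overexpression libraries. CHD2 was 2.04-fold lower in knockdown than in wild type (log2 fold -1.04 ± 0.11, adjusted p = 8.84e-09). It was 1.504-fold higher in overexpression than in wild type (log2 fold 0.59 ± 0.11, adjusted p = 3.66e-06). No library of a group overlapped those of another, and each two-sided exact permutation test with n = 6 per group gave p = 0.00216, the smallest that 924 rearrangements allow. The margin was narrow between wild type replicate 3, at 3925.5, and overexpression replicate 4, at 3968.9. CHASERR (ENSG00000272888.6, chromosome 15, 92882707 to 92899701), the long noncoding RNA gene next to CHD2, moved the same way, from 568 ± 76.2 in knockdown through 765 ± 39.3 in wild type to 937 ± 42.3 in overexpression libraries. On the deposited scale the CHD2 rise was 0.43, and it was 0.21 after quantile normalization, with adjusted p = 0.00666.

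**Figure D2:**
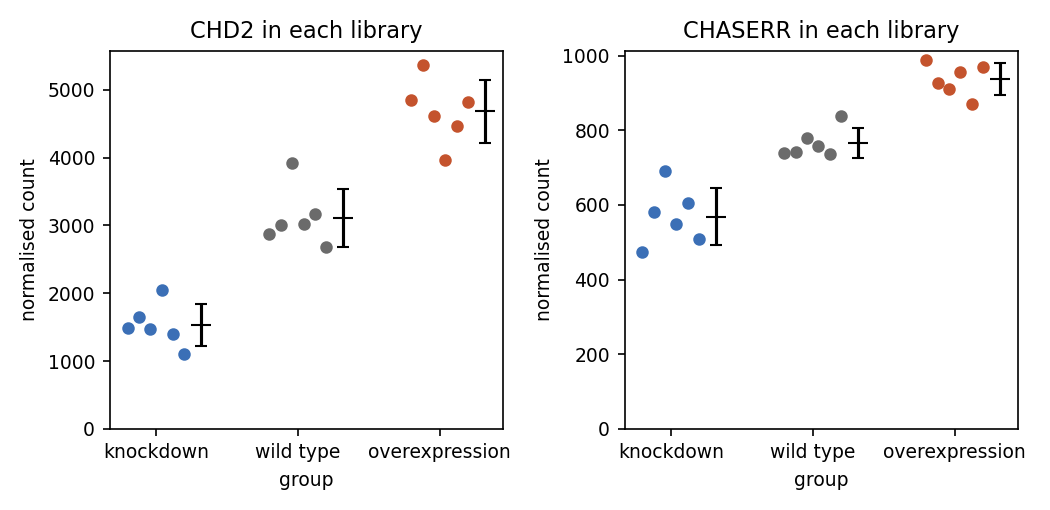
Normalised counts of CHD2 (left) and CHASERR (right) in each of the 18 libraries, with 1 point per library and the mean ± SD of each group beside the points. CHD2 lay at 1528 in knockdown, 3112 in wild type and 4678 in overexpression on average, with no overlap between groups.

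The comparison of knockdown with wild type asked which transcripts differed when CHD2 was low. STC1, which encodes the secreted glycoprotein stanniocalcin, rose from 51.2 ± 19.2 to 34169 ± 707 normalised counts (log2 fold 9.44 ± 0.22). Several keratin and cell junction genes fell to near 0, with KRT19 at 36.5 ± 14.3 against 8589 ± 295 and JUP, the junction protein plakoglobin, at 23.3 ± 9.96 against 7479 ± 421. KITLG, the ligand of the KIT receptor, fell from 21415 ± 411 to 155 ± 18.8, and BMP4, a secreted growth factor of the TGF-beta family, from 16217 ± 146 to 119 ± 9.70.

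STC1 (ENSG00000159167.11) lies on chromosome 8 at 23841915 to 23854807. The other large rises were S100A2, a calcium-binding protein of the S100 family (76.6-fold), C2CD2 (26.2-fold), LAMB3, a chain of basement membrane laminin (21.4-fold), RAB3IP (20.8-fold) and the sialyltransferase gene ST6GALNAC4 (17.6-fold). TM4SF1 rose from 26.5 ± 16.1 to 8566 ± 110. BST2, an interferon-inducible protein that holds budding virus at the cell surface, rose from 18.2 ± 3.99 to 5378 ± 116. Among the large falls, AKAP12, a scaffold of protein kinase A, dropped from 38176 ± 1548 to 629 ± 35.6, DCBLD2 from 30145 ± 427 to 1332 ± 61.4, and PDP1, a phosphatase of pyruvate dehydrogenase, from 19078 ± 718 to 699 ± 81.2. ITGB4, the integrin chain of hemidesmosomes, went from 9512 ± 629 to 36.2 ± 24.9. ARHGAP29, MYOF and LAPTM4B were 175-fold, 67.9-fold and 195-fold lower. The highest adjusted p among the named rises was 2.07e-26 and among the named falls 5.06e-25. In all, 7182 of 8300 tested genes (86.5%) passed the threshold, 3932 higher and 3250 lower in knockdown (which direction prevailed depended on scaling and filter). Of them 484 differed by at least 1 on the deposited scale, where CHD2 itself differed by only -0.648. On log2 counts of 16143 genes, 2052 called genes were higher by at least 1 log2 unit and 3380 lower by as much.

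The epithelial junction and keratin list moved as a group in knockdown. Of its 16 tested members 14 fell and 0 rose (camera adjusted p = 2.73e-07, and adjusted p = 0.0253 with an estimated correlation). ESRP1, an epithelial splicing regulator, fell from 3595 ± 75.8 to 20.7 ± 9.97, and KRT8 from 25717 ± 658 to 1352 ± 141. Of 3 mesenchymal transition genes that passed the filter, all rose. ZEB1, a transcriptional repressor of epithelial genes, rose from 86.0 ± 17.7 to 7617 ± 228. With the filter lowered to 10 normalised counts, 4 of 11 mesenchymal transition genes rose and 3 fell. Beside this loss of epithelial transcripts, CD68, a lysosomal protein abundant in macrophages, stood at 14129 ± 239 against 76.6 ± 10.1 in wild type, and the fibroblast collagen gene COL1A1 at 17.8 ± 16.1 against 406 ± 39.1. With the lower filter, 2 of 3 leukocyte markers rose and 1 fell, 0 of 3 fibroblast markers rose and 2 fell, and of 2 endothelial markers 1 rose and 1 fell. The lysozyme gene LYZ was among the leukocyte rises, at only 48.2 ± 44.7 against 18.8 ± 14.2 in wild type. It was abundant in overexpression libraries, so carry-over cannot be told apart from expression at this level.

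Transcripts of the mitochondrial genome fell in knockdown, all 13 of them (camera adjusted p = 8.21e-07, but adjusted p = 0.318 with an estimated correlation). MT-ND1 was 3.42-fold lower and MT-CO3 2.98-fold lower, while MT-ND4 and MT-CO2 were 2.83-fold and 2.79-fold lower. The mitochondrial share of the normalised counts was 2.25% ± 0.0544 in knockdown and 5.56% ± 0.212 in wild type libraries (SD, n = 6). G2/M genes also fell, 16 of 22 with 3 rising (camera adjusted p = 0.00242, but adjusted p = 0.172 with an estimated correlation). KIF20A, a mitotic kinesin, was 3.26-fold lower, the kinase TTK of the spindle checkpoint 2.89-fold, BIRC5, the survivin gene, 2.38-fold and CDC20, an activator of the anaphase-promoting complex, 1.73-fold lower.

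Cytosolic ribosomal protein genes rose in knockdown, 22 of 24 with 1 falling (camera adjusted p = 0.000159, but adjusted p = 0.318 with an estimated correlation). RPL35 rose 2.47-fold, RPL7A 2.32-fold, RPL30 1.87-fold and RPL3 1.52-fold. Of 11 Wnt/beta-catenin targets 9 fell and 2 rose (camera adjusted p = 0.00285, but adjusted p = 0.172 with an estimated correlation). DKK1, a secreted Wnt antagonist, went from 8713 ± 384 to 18.9 ± 16.7, the transcription factor gene SOX4 from 10928 ± 350 to 525 ± 45.3, and CD44, an adhesion receptor for hyaluronan, from 12452 ± 474 to 3367 ± 232. Counts adjusted over the list alone were the same as those over all genes for each of these 5 lists. Lists close to CHD2 did not pass: of 14 CHD family remodelers 11 rose and 3 fell (camera adjusted p = 0.351), and of 10 H3.3 deposition genes and CHD2 partners 8 fell and 1 rose (camera adjusted p = 0.0769, and adjusted p = 0.0443 after quantile normalization). The Wnt call ended with a stricter filter (adjusted p = 0.0631) and on log2 counts (adjusted p = 0.137). Genes at fewer than 50 counts in a group, such as KRT19, JUP, ITGB4 and DKK1 in knockdown, are uncertain at the low end. The same holds above 50 counts for genes far more abundant in another group, such as STC1 in wild type libraries. Genes abundant in 1 group were found elsewhere at median shares of 0.0527% to 0.588% of that level, so the folds of such genes are uncertain too.

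The comparison of overexpression with wild type asked which transcripts differed when CHD2 was high. LYZ, which encodes lysozyme, rose from 18.8 ± 14.2 to 43726 ± 809 normalised counts, and TGM2, a transglutaminase that crosslinks proteins, from 282 ± 45.8 to 31872 ± 929. Type I interferon response genes rose together, with IFI27 at 12608 ± 200 against 23.4 ± 8.84. Keratins rose further, KRT8 4.47-fold to 115056 ± 3478 and KRT18 5.51-fold to 83389 ± 2171. FSCN1, an actin-bundling protein, fell from 10058 ± 315 to 41.8 ± 8.27.

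LYZ (ENSG00000090382.6) lies on chromosome 12 at 69348341 to 69354234 and FSCN1 (ENSG00000075618.17) on chromosome 7 at 5592823 to 5606655. The serine protease gene KLK6 rose from 409 ± 34.5 to 23474 ± 482, and CTSD, the lysosomal protease cathepsin D, from 2606 ± 114 to 37561 ± 1722. S100A4, a calcium-binding protein linked to cell motility, rose 12.1-fold, ARHGAP23 21.5-fold, the sialyltransferase gene ST3GAL1 20.3-fold, and TNS4, a tensin of focal adhesions, 10.3-fold. TM4SF1 rose to 6688 ± 138. Other falls were in PALLD, the gene of the cytoskeletal protein palladin (43.9-fold lower), DBN1, the gene of drebrin (35.8-fold lower), and EZR, the gene of ezrin (4.92-fold lower). AKAP12, PDP1 and KITLG fell as they did in knockdown, to 686 ± 39.6, 351 ± 47.8 and 2072 ± 70.9. CPOX, an enzyme of heme synthesis, was 34.7-fold lower, AP3S1, a subunit of a vesicle adaptor, 10.8-fold lower, and the amino acid transporter gene SLC38A2 6.34-fold lower. The highest adjusted p among the named rises was 6.59e-24 and among the named falls 9.86e-24. In all, 7455 of 8300 tested genes (89.8%) passed the threshold, 4077 higher and 3378 lower in overexpression (again depending on scaling and filter). Of them 650 differed by at least 1 on the compressed deposited scale. On log2 counts of 16143 genes, 3092 called genes were higher by at least 1 log2 unit and 3484 lower by as much.

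All 11 tested members of the type I interferon response rose in overexpression (camera adjusted p = 0.000234, and adjusted p = 0.0164 with an estimated correlation). OAS1 and OAS3, which sense double-stranded RNA, rose from 15.3 ± 7.97 to 5584 ± 122 and from 2489 ± 92.2 to 18738 ± 528, and IFI6 rose 25.2-fold. With the filter lowered to 10 normalised counts, all 24 listed members rose. In the epithelial list 14 of 16 rose and 1 fell (camera adjusted p = 0.00305, but adjusted p = 0.148 with an estimated correlation). CLDN4, a tight junction claudin, rose 4.68-fold and CDH1, the gene of E-cadherin, 3.81-fold. The epithelial call also ended with a stricter filter (adjusted p = 0.0781). Beside these groups LYZ, which is also abundant in phagocytes, was among the leukocyte markers that moved, and CD14, a monocyte receptor, stood at 323 ± 15.0 against 6.01 ± 4.09. With the lower filter, all 3 leukocyte markers and both endothelial markers rose, and of 3 fibroblast markers 0 rose and 2 fell.

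Genes of the ATF4 amino acid response fell in overexpression, 11 of 14 with 3 rising (camera adjusted p = 0.00395, and adjusted p = 0.0335 with an estimated correlation). PHGDH and PSAT1, enzymes of serine synthesis, were 6.25-fold and 3.303-fold lower. ASNS, asparagine synthetase, was 4.66-fold lower, and DDIT4, an inhibitor of mTOR signalling, 6.45-fold lower. All 13 transcripts of the mitochondrial genome fell (camera adjusted p = 0.000234, but adjusted p = 0.448 with an estimated correlation). MT-ND2 was 2.42-fold lower and MT-ND4 2.36-fold lower, but MT-CO2 was 1.24-fold lower, and it was higher by 0.0913 on the deposited scale after quantile normalization. The mitochondrial share of the normalised counts was 3.12% ± 0.0871 in overexpression libraries (SD, n = 6). Counts adjusted over the list alone were the same for each of these 4 lists. KRT8 and KRT18 overlap on chromosome 12 and have pseudogenes, and the use of strand is not stated, so their levels are uncertain.

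**Figure D3:**
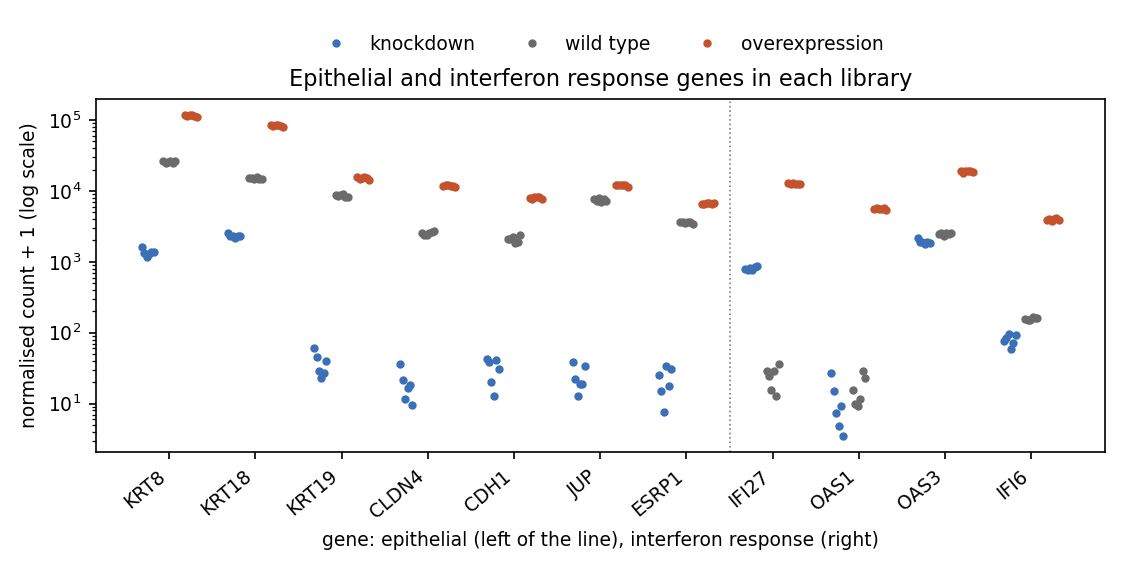
Normalised counts plus 1 on a log axis for 7 epithelial genes (left of the dotted line) and 4 interferon response genes (right), with 1 point per library and 6 libraries per group. The epithelial genes were lowest in knockdown and highest in overexpression, and the interferon response genes were highest in overexpression, whereas OAS1 and IFI6 differed between knockdown and wild type in a direction that turned with quantile normalization.

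The comparison of overexpression with knockdown set high against low CHD2. CHD2 was 3.06-fold higher (log2 fold 1.63 ± 0.11, adjusted p = 8.46e-13). KRT8 was 85.1-fold higher and KRT18 35.7-fold higher, and CLDN4 stood at 11832 ± 295 against 17.9 ± 9.48. STC1 was lower in overexpression, at 40.6 ± 14.7. AXL, a receptor tyrosine kinase, was 108-fold lower, and MT2A, a metal-binding metallothionein, 24.8-fold lower.

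Further genes with large rises were LYZ, TGM2, KLK6, ARHGAP23 (302-fold), S100A4, TNS4, LGALS3BP, which encodes a galectin-binding secreted protein (349-fold), and ST14, the gene of the protease matriptase (699-fold). In knockdown ARHGAP23 stood at 88.1 ± 32.3, LGALS3BP at 62.8 ± 18.4 and ST14 at 28.0 ± 16.1. Genes abundant in overexpression were found in knockdown libraries at median shares of 0.0527% to 0.309% of that level. Such low levels, and the folds that rest on them, are therefore uncertain. Further falls were in C2CD2 (36.1-fold lower), S100A2 (25.9-fold lower), the adaptor gene SH2B3 (87.9-fold lower), the ubiquitin ligase gene SMURF2 (20.5-fold lower), ST6GALNAC4 (16.4-fold lower) and the tyrosine kinase gene ABL2 (17.6-fold lower). The highest adjusted p was 3.19e-28 among the named rises and 7.89e-26 among the named falls. In all, 7522 of 8300 tested genes (90.6%) passed the threshold, 3836 higher and 3686 lower in overexpression. Of them 875 differed by at least 1 on the compressed deposited scale. On log2 counts of 16143 genes, 3730 called genes were higher by at least 1 log2 unit and 3127 lower by as much.

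All 16 tested epithelial genes were higher in overexpression than in knockdown (camera adjusted p = 1.37e-06, and adjusted p = 0.0191 with an estimated correlation), and so were all 11 interferon response genes (camera adjusted p = 7.20e-05, and adjusted p = 0.0121 with an estimated correlation). Of 22 G2/M genes 19 were higher and 1 was lower (camera adjusted p = 0.00311, but adjusted p = 0.212 with an estimated correlation). TOP2A, a DNA topoisomerase of dividing cells, was 3.76-fold higher, CCNB2, a mitotic cyclin, 2.46-fold and the proliferation marker MKI67 1.75-fold higher. Of the 13 mitochondrial transcripts 12 were higher and 1 was lower (camera adjusted p = 0.0309, but adjusted p = 0.886 with an estimated correlation). That call ended after quantile normalization (adjusted p = 0.0949) and with a stricter filter (adjusted p = 0.0952). Counts adjusted over the list alone were the same for each of these 4 lists.

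**Figure D4:**
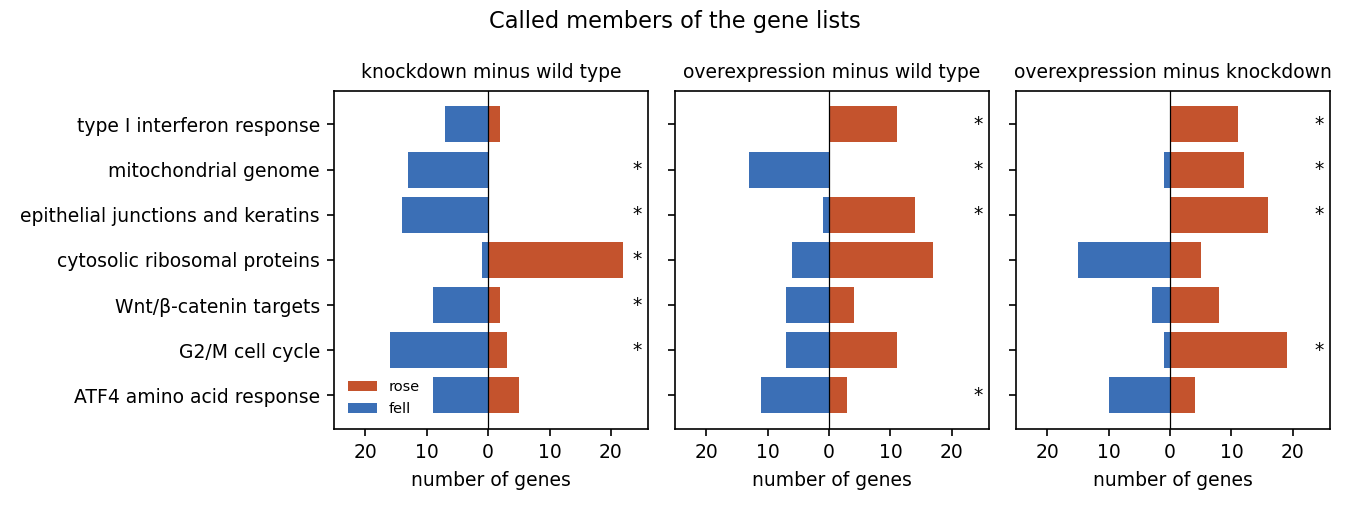
Number of tested members of 7 gene lists that rose (red, to the right) or fell (blue, to the left) in each comparison, where a star marks a list with a camera adjusted p under 0.05. All 11 interferon genes rose against both other groups and 14 of 16 epithelial genes fell in knockdown, whereas the majority turned with quantile normalization for interferon genes in knockdown (2 up and 7 down, then 6 and 3) and, in overexpression against wild type, for ribosomal proteins (17 and 6, then 9 and 10) and G2/M genes (11 and 7, then 5 and 12).

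Genes with the same order over the 3 groups as CHD2 were led, on the deposited scale, by S100A4, KRT18, KRT8, TNS4 and MAL2, a protein of apical membrane transport. That order alone does not tie them to CHD2, since the labels cannot separate CHD2 from other differences between the groups. MAL2 stood at 38.1 ± 30.8 in knockdown, 4015 ± 127 in wild type and 19281 ± 1037 in overexpression libraries, and S100A4 at 44.9 ± 43.2, 3024 ± 193 and 36555 ± 1035. TNS4 stood at 30.1 ± 22.4 in knockdown and at 2345 ± 110 in wild type. The opposite order held for SMURF2, at 19325 ± 748, 5687 ± 189 and 941 ± 31.7. AKAP12, PDP1, PALLD and CPOX were instead lower in both groups than in wild type, and BST2 and TM4SF1 higher in both.

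Of the genes called against wild type in both groups, 2461 moved in opposite directions and 4013 in the same direction. The opposite genes were 1210 that rose in knockdown and fell in overexpression and 1251 that did the reverse. Those moving the same way were 2299 that rose in both and 1714 that fell in both. Independent lists of these sizes would share 3197 genes with opposite and 3254 with the same direction, so opposite genes were fewer and same-direction genes more numerous than that. Both comparisons share the wild type libraries. With a separate 3 of them for each group the counts were 2314 and 3808 in 1 division and 2285 and 3831 in the other. Simulated groups without change gave 0 and 0. Hardly any gene can be called without a change, so the simulation cannot show how shared libraries act on genes that differ. Neither check covers a difference shared by all wild type libraries, which would move genes the same way in both comparisons. The log2-like differences of the comparisons had a correlation across genes of 0.206 and a covariance of 0.0699, and the simulated groups had a mean correlation of 0.501 with a covariance of 0.000386.

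In each comparison many tested genes changed more than CHD2 itself. In knockdown against wild type 1424 of 8300 genes (17.2%) had a larger absolute log2 fold than CHD2, in overexpression against wild type 3920 (47.2%), and in overexpression against knockdown 1118 (13.5%). Some genes were on in 1 group and all but absent in another. In knockdown 16 genes exceeded a mean of 500 normalised counts while staying under 3 in wild type, and 57 did the reverse. In overexpression against wild type these numbers were 39 and 63, and in overexpression against knockdown 87 and 24.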

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

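Chosen only after the results were seen were the tests of a graded response, of the authors' scaling, of other cell types and of carry-over between libraries. Those of copy number were fixed before their results were seen.

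For each named gene and for 4 measures of depth and composition, the highest or lowest library of each group was compared with the other 5, as the gap to its neighbour over the group's whole range. Of 303 such groups 22 passed Dixon's critical value, and chance marks about 1 in 20, or 15.2. In knockdown libraries the ratios were 0.700 for RAB3IP (replicate 6), 0.680 for OAS3 (replicate 1), 0.687 for STMN3 (replicate 3), 0.677 for FCGBP (replicate 1) and 0.698 for HES1 (replicate 2). In wild type libraries they were 0.767 for TM4SF1 (replicate 5), 0.714 for PDP1 (replicate 2), 0.721 for AXL (replicate 4), 0.762 for BIRC5 and 0.763 for TTK (replicate 2), 0.665 for SOX4 (replicate 6), 0.713 for KLF4 (replicate 2) and 0.895 for HOXB3 (replicate 6). In overexpression libraries they were 0.626 for C2CD2 (replicate 1), 0.692 for DBN1 (replicate 6), 0.682 for MT2A (replicate 3), 0.693 for ABL2 (replicate 2), 0.839 for JUP (replicate 6), 0.6254 for KIF20A (replicate 3), 0.715 for PHGDH (replicate 3), 0.644 for CD68 (replicate 6) and 1 for MAGEB2 (replicate 5, at 1.27 counts where the others had 0).

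The 3 groups differed in most of the kept genes, from KRT8 and STC1 to the ribosomal proteins, while CHD2 changed by no more than 3.06-fold. A response graded with CHD2 would move genes in opposite directions in knockdown and overexpression, but at most 37.8% of the genes called in both did so when each comparison had its own wild type libraries. A difference shared by all wild type libraries would remain in both divisions and add genes that move the same way. This share therefore cannot decide on a graded response beside such a difference. Scaling by a single factor per library cannot change ranks within it, and the highest rank correlation between libraries of different groups was 0.729 against a lowest of 0.991 within groups. Scaling that differs between the genes of a library can change ranks, and the sources do not say whether it was used. Copy number differences between the cells stay open, since 2, 3 and 1 of 131 windows of 20 Mb (knockdown against wild type, overexpression against wild type, overexpression against knockdown) went beyond all 1000 permutations, whose limits of 0.75, 0.91 and 1.04 on the log2 scale would hide a gain of 1 copy beside a pair, though the limits for the comparisons with wild type would not hide the loss of 1 copy of a pair. An ungraded response to CHD2 and cell populations that had diverged or been derived separately also stay open, as the labels cannot separate them from the groups.

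Epithelial genes such as KRT19, CLDN4 and ESRP1 were near 0 in the knockdown libraries. A large admixture of fibroblasts, leukocytes or endothelial cells may dilute epithelial transcripts, yet the highest mean among COL1A1, COL1A2, COL3A1, PTPRC, TYROBP, PECAM1 and VWF in knockdown was 17.8 normalised counts, which argues against it. CD68 at 14129 ± 239 was the exception among leukocyte markers, and it came without PTPRC (6.54 ± 3.59). A response to knockdown of CHD2 and another cell population under the knockdown label both stay open and were not tested.

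Transcripts abundant in overexpression libraries, such as LYZ, S100A4 and KLK6, were present at low and uneven levels in the knockdown libraries. Reads or RNA carried over between libraries may account for this: the shares of 49 such genes, divided at random into 2 sets, rose and fell together over the 6 knockdown libraries (Pearson r = 0.972, permutation p = 0.0194, adjusted p = 0.117 over 6 relations; Spearman rho = 0.886, permutation p = 0.0333), with shares of 0.0527% to 0.309%. Without the 2 libraries farthest from the median, replicates 1 and 2, r was 0.559, so the relation rests on them. The other 5 relations had r of 0.771 (overexpression genes in wild type), 0.232 and -0.875 (wild type genes in knockdown and overexpression), and 0.356 and 0.469 (knockdown genes in wild type and overexpression). Without the 2 farthest libraries these were, in the same order, -0.575, 0.956, -0.287, 0.176 and 0.786, so whether the pattern was general stays open. True expression that differs between the knockdown libraries was not tested.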

How the results depend on the processing

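Chosen only after the data were seen were the analysis on log2 of normalised counts and the one without knockdown replicates 1 and 2. CHD2 kept its direction and its call in both comparisons with wild type under the alternatives run for it, with differences of -0.699 to -0.599 and 0.401 to 0.481 when each library was left out in turn. Gene counts changed with the filter, the scale and the difference required. For knockdown against wild type, overexpression against wild type and overexpression against knockdown they were 16686, 18187 and 17056 with no filter. They were 2464, 2538 and 2550 with the stricter filter. On log2 counts, where scale and filter both changed, they were 13036, 13750 and 13614. With a difference of at least 1 on the compressed deposited scale among the same 8300 genes they were 484, 650 and 875. Of the called genes 54.7%, 54.7% and 51% were higher, but 51.8%, 47.9% and 46.5% after quantile normalization, 49.8%, 48.4% and 48.8% with median centring, 43.4%, 46.9% and 53.2% with no filter, 54.1%, 60.8% and 57.7% with the stricter filter, 47.4%, 49.2% and 51.5% on log2 counts and 44.4%, 66.9% and 64.2% with a difference of at least 1, so which direction prevailed depended on scaling and filter. With no filter, the stricter filter, log2 counts and a difference of at least 1, genes with opposite directions numbered 4156, 834, 4085 and 44, and genes with the same direction 9254, 1429, 7226 and 96. Leaving out each library in turn gave 7118 to 7175, 7406 to 7432 and 7479 to 7500 genes, 2415 to 2464 opposite and 3959 to 4025 same-direction genes, and 5 to 5, 4 to 4 and 4 to 4 lists.

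With the replicate number as a block, the counts were 7180, 7453 and 7516 genes, 2451 opposite and 4018 same-direction genes, and 5, 4 and 4 lists. Without knockdown replicates 1 and 2 they were 7048, 7449 and 7435, then 2406 and 3944, and 5, 4 and 4 lists.

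Called lists numbered 1, 2 and 2 with an estimated correlation, 28, 30 and 30 with fry, 13, 13 and 13 of 42 lists with no filter, and 7 in overexpression against wild type after quantile normalization; apart from the larger number of lists without a filter, the cause was not tested. Camera compares a list with the other genes and fry compares it with no change, so their directions need not be the same. With fry 18 lists that camera did not call were called in the direction opposite to camera's, and what set the direction of each list was not tested. Neither direction need have the sign of the list's mean difference. In knockdown against wild type the mean differences of these lists were 0.0338 for glycolysis, 0.0463 for hypoxia, 0.101 for immediate early genes, 0.0889 for invasion proteases, 0.115 for NRF2 targets, 0.422 for TGF-beta/SMAD targets and 0.214 for YAP/TAZ targets. In overexpression against wild type they were 0.217 for heat shock, 0.216 for NF-kB, 0.00664 for NRF2 targets, 0.0268 for splicing factors and 0.193 for stemness markers. In overexpression against knockdown they were 0.0243 for CHD family remodelers, 0.188 for heat shock, 0.298 for invasion proteases, 0.00228 for end joining, -0.108 for NRF2 targets and 0.127 for TGF-beta/SMAD targets.

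Quantile normalization reversed 7 differences of named genes, and the cause was not tested: in overexpression against wild type STC1 0.0679, ITGB4 -0.0277, MT-CO2 0.0913, RPL7A -0.0850 and MKI67 -0.0388, and in knockdown against wild type OAS1 0.156 and IFI6 0.193. Of all named gene results by setting, 5966 kept direction and call, 18 lost the call and 18 gained it. At this depth, levels under about 3 reads in a library are not told apart from 0.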

Other observations

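Chosen only after the results were seen were the gene families below and the tests against other divisions of the libraries.

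Short gene lists fixed in advance held further differences, measured on genes with at least 10 normalised counts. Goblet and secretory markers went apart in overexpression against wild type, where 7 of 10 rose and 3 fell (camera adjusted p = 0.325 on log2 counts): CREB3L1, a transcription factor of secretory cells, stood at 1926 ± 55.2 against 4.83 ± 1.72, while KLF4 stood at 115 ± 17.9 against 1001 ± 75.9 and FCGBP, a mucus protein, at 85.8 ± 15.7 against 360 ± 34.1. Of 9 neuronal genes repressed by REST, 7 fell and 1 rose against wild type in knockdown (camera adjusted p = 0.0450 on log2 counts), and the same numbers held in overexpression (adjusted p = 0.0667), with STMN3 at 401 ± 20.7, 3491 ± 79.7 and 212 ± 14.1 and UNC13A, a gene of synaptic vesicle priming, at 17.0 ± 10.1, 2046 ± 159 and 2.53 ± 1.11 in knockdown, wild type and overexpression. Of 11 Notch targets 9 fell and 2 rose in overexpression against wild type (camera adjusted p = 0.0667 on log2 counts), but HES1, a Notch-induced repressor, rose from 252 ± 7.10 to 1032 ± 50.3. Of 14 antigen presentation genes 11 rose and 2 fell in knockdown against wild type (camera adjusted p = 0.00326 on log2 counts, and adjusted p = 0.177 among the kept genes). PSMB8, an immunoproteasome subunit, stood at 702 ± 36.4 against 10.99 ± 3.503.

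Genes of families chosen after their values were seen also differed between the groups. Of 39 HOX genes, which set position along the body axis, 18 reached 100 normalised counts in knockdown, 15 in wild type and 20 in overexpression libraries, with HOXB9 at 895 ± 47.1, 342 ± 5.54 and 6867 ± 150 and HOXB3 at 247 ± 7.71, 85.4 ± 22.4 and 2770 ± 69.3. Others went the other way, with HOXC8 at 233 ± 14.3, 28.9 ± 4.32 and 15.8 ± 2.10 and HOXA9 at 1211 ± 61.9, 1422 ± 42.7 and 815 ± 22.8. Among 73 germline-restricted genes 9 reached 100 counts in a group, 1 in knockdown, 6 in wild type and 4 in overexpression. GTSF1 stood at 7.59 ± 4.31, 3253 ± 100 and 2.39 ± 1.99, MAGEB2 at 5.27 ± 3.05, 2778 ± 107 and 0.212 ± 0.519, PRAME at 1509 ± 55.3, 1043 ± 40.2 and 11.2 ± 6.43, and MAGEA12 at 2.84 ± 1.79, 2.12 ± 1.66 and 387 ± 36.1. Of 37 detoxification genes 11 reached 100 counts in overexpression, 3 in knockdown and 2 in wild type. GPX2, a glutathione peroxidase of the gut epithelium, stood at 21.3 ± 22.8, 10.8 ± 9.02 and 22242 ± 861, and CYP3A5, a cytochrome P450 gene, at 12.5 ± 2.27, 9.71 ± 5.26 and 2771 ± 75.4. Of 13 repair and tumour suppressor genes 9 reached 100 counts in knockdown, 12 in wild type and 13 in overexpression. Among them the cell cycle inhibitor gene CDKN2A stood at 12.4 ± 1.99, 2052 ± 78.0 and 1742 ± 87.0, and SMAD4 at 1249 ± 72.6, 1890 ± 101 and 256 ± 48.6. Whether the differences in these families came from CHD2 or from separate cell populations was not tested.

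Each count was set beside 100 divisions of the same libraries into groups of the same sizes, the real one included. For genes called in knockdown against wild type 1 of 100 divisions was as large, the real one with 7182, and the highest other had 5921. In overexpression against wild type it was 1 of 100, with 7455 and 6384, and in overexpression against knockdown 1 of 100, with 7522 and 6522. For genes moving in opposite directions it was 1 of 100, with 2461 and 0, and for the same direction 1 of 100, with 4013 and 3091. Differences within groups made up 1.38% of the total sum of squares, so divisions that mix the groups have a larger spread. The labelled division would then give the highest count in any case, and these 5 ranks do not show whether chance can be excluded. Chance differences between cultures cannot be excluded, since no label says that the libraries of a group came from separate cultures. The numbers of called lists were reached by 30 of 100 divisions in knockdown against wild type (5 lists, highest other 6), by 31 in overexpression against wild type (4 lists, highest other 7) and by 32 in overexpression against knockdown (4 lists, highest other 5). Unequal divisions keep part of the difference between the groups, so these list counts do not show whether chance can be excluded.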
